A study of Homo sapiens with 24 samples.

How the data were processed

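The data are 24 libraries of human HEK293 cells, prepared by MARS-Seq, a method that counts short tags near the 3' ends of polyadenylated transcripts. Cells of a line labelled as a TAF1 temperature-sensitive mutant carried either unedited RPS26 (WT) or a CRISPR deletion that removes the C terminus of the endogenous RPS26 protein (RPS26dC). They were left untreated or kept for 4 h in medium without glucose and with dialysed serum, then given 100 µg/ml cycloheximide for 5 min, lysed and run on a sucrose gradient. RNA was taken from unfractionated lysate (Input), from the part of the gradient holding 2 to 5 ribosomes per mRNA (Light) and from the part holding 6 or more (Heavy). Each of the 12 groups of genotype, treatment and fraction held 2 libraries. Equal amounts of RNA went into the libraries, so a shift in the total amount of mRNA on polysomes could not be read from them.

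The deposited table gives counts, as whole numbers per protein-coding gene and library, with the sequencing lanes of a library added together. Per the labels, the authors' processing notes name Bowtie2, featureCounts and DESeq2 and the builds hg38 and GRCh38. Versions, the role of each tool, the treatment of molecular identifiers, the strand setting and the annotation release are not given in the sources used here. The table holds 19933 genes, of which 19829 were matched by identifier to GENCODE release 29, whose GRCh38 coordinates are printed. Its 13 mitochondrially encoded genes had 0 counts in every library, so their transcripts were not analysed here. Among 1353 pairs of overlapping genes with enough counts, 169 had nearly equal counts, 83 of them on opposite strands, so a read could be counted for both genes of a pair. Library totals ran from 2.96 to 12 M counts, with M for mega, with a median of 7.01 M. Count floors cover counting error alone, unlike the SDs and standard errors given with ±.

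Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes with too few counts were removed with filterByExpr, which left 13886, library sizes were scaled by TMM, and a single quasi-likelihood model with a coefficient for each of the 12 groups was fitted to all 24 libraries with 12 residual degrees of freedom. The square root of the common dispersion was 0.237. In all, 16 comparisons were tested, 2-sided, each adjusted by Benjamini-Hochberg over the genes with a threshold of 0.05: the genotypes in Input, starvation in Input, the difference between these responses, the same questions for the Heavy over Input and Heavy over Light ratios as differences of differences, and Heavy against Input and against Light in untreated WT. The difference between the starvation responses of the genotypes was not tested for Heavy over Light. Since 2 libraries per group share a pooled spread, and the labels do not say whether the numbers 1 and 2 are separate cultures, p-values measure the spread between these samples. The pool spans both genotypes, although RPS26dC libraries numbered 1 and 2 differed in 1843 genes and those of WT in 16. Thus WT p-values carry some of the RPS26dC spread, and p-values of the genotype comparisons in Input may be too small. Within RPS26dC the difference between the numbers lies on both compared sides, so p-values there may instead be too large. Fits with a term for the number called more genes in the RPS26dC starvation comparisons, as given under the dependence on processing. Counts of calls therefore do not rank the responses of the genotypes. Counts were also simulated at these depths, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those averaging at least 4 log2 CPM (defined below), so recovery among rarer genes was not simulated. The Input starvation comparison recovered 43 and 99, and the Heavy over Input genotype comparison 16 and 89. The Heavy over Light starvation comparison recovered 10 and 93, and the Input response difference 16 and 83.

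Before the data were examined, 27 gene lists were written, covering translation, energy metabolism, stress responses, the cell cycle, and markers of the line and of other cell types. The 25 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move in a common direction, were the alternatives. Of 400 tests, 93 passed with the preset correlation and 21 of these with the estimated correlation. Calls within a list were also counted after adjustment over the list alone.

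The genes named in the text were chosen by a rule set before the data were examined. For each comparison it took up to 12 genes in each direction with the largest changes among those that passed, averaged at least 4 log2 CPM (counts over the scaled library size in M) and had no overlap between the replicate values of the compared sides, then up to 4 members of each list with the smallest p, and 25 genes named in advance. The text names a part of these, and some results are not reported here. In every gene named as having passed, the values of both libraries on one side lay beyond those of both libraries on the other. TXNIP and ARRDC4, named in advance as glucose-responsive genes, had 384 and 323 counts over all libraries and are not reported gene by gene.

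Alternatives planned in advance were DESeq2 1.42.0, size factors by relative log expression or by library totals, no filter on low counts, a replicate number term, a term for genotype, treatment and number together, a fit to the compared groups alone, Light or the mean of both fractions in place of Heavy, and leaving out each library in turn. Added after the data were seen were a replicate number term within each genotype and the removal of all RPS26dC libraries of either number. For the gene lists, library totals and leaving out each library were not among the planned settings either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.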

Results

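Translation was profiled in HEK293 cells, a human embryonic kidney line, to ask how the C-terminal tail of the small-subunit ribosomal protein RPS26 bears on which mRNAs sit on polysomes, in fed cells and after glucose withdrawal. RPS26dC cells lack that tail and WT cells keep it. For both genotypes, untreated and starved for 4 h, Input, Light and Heavy RNA was sequenced in 2 libraries each. Totals ranged from 2.96 to 6.54 M counts for Input, 5.4 to 12 M for Light and 4.83 to 10.5 M for Heavy. Over genes, log2 CPM of replicates correlated with Pearson's r of 0.948 to 0.9735, genes not being independent replicates. The leading principal component held 31% of the variance, 96.6% of it between genotypes, and the next held 26.2%, 89.6% of it between fractions. RPS26dC libraries numbered 1 and 2 differed from each other in 1843 of 13603 genes across the 6 groups, against 16 of 13075 in WT. Among genes chosen after their values were seen, CCN2, ATF3 and SESN2 were higher in number 2 by 1.40, 1.02 and 1.03 on the log2 scale, and NOTCH3 differed by -1.90. Changes below are log2 differences with their standard error, from 2 libraries per group.

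The edited gene itself was counted thinly. RPS26 (ENSG00000197728, chromosome 12, 56041351 to 56044697) had 7 to 171 counts per library, between 1.05 and 16.8 CPM with a median of 5.15. Its Input level was 5.79 ± 2.12 CPM in untreated WT and 9.85 ± 1.47 in untreated RPS26dC (SD, n = 2), a difference of 0.76 ± 0.49 (adjusted p = 0.35) that did not pass. In starved cells the difference was 1.06 ± 0.52 (adjusted p = 0.19). A 3' tag may lie outside the deleted coding part, and RPS26 has many pseudogene copies, so these counts do not test the edit. TAF1, the gene mutated in the parental line, did not pass either, at -0.69 ± 0.36 (adjusted p = 0.24) in untreated and -0.85 ± 0.38 (adjusted p = 0.14) in starved cells.

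Loss of the RPS26 tail went with a broad difference in total mRNA in untreated cells. Neurofilament transcripts stood out. NEFM (ENSG00000104722, chromosome 8, 24913012 to 24919098) was at 40.5 ± 3.75 CPM in WT and 1820 ± 301 in RPS26dC (SD, n = 2), a rise of 5.49 ± 0.20 (adjusted p = 2e-16). Its neighbour NEFL rose by 3.18 ± 0.21. Also higher were the matrix and adhesion genes TNC (6.47 ± 0.45), CD44 (6.58 ± 0.45) and CCN3 (6.04 ± 0.30), and the growth regulators MYC (2.43 ± 0.26) and KLF4 (4.06 ± 0.35). Further genes that rose were the growth arrest gene GADD45G (5.76 ± 0.57), the zinc finger gene ZNF331 (6.50 ± 0.41) and the imprinted, retrotransposon-derived PEG10 (7.61 ± 0.67). HSPA1A, an inducible heat shock protein, was higher by 6.69 ± 0.54, at 9.88 ± 5.56 CPM in WT and 1020 ± 341 in RPS26dC (SD, n = 2). Its near-identical neighbour HSPA1B stood at 249 ± 38.4 and 157 ± 54.5 CPM, so counts of the 2 genes did not move together. How reads that match both were assigned is not given in the sources used here. Among the named genes the largest fall was in IRS4 (ENSG00000133124, chromosome X, 108732482 to 108736409), an insulin receptor substrate abundant in HEK293 cells, from 262 ± 24.6 to 0.823 ± 0.142 CPM, or -8.30 ± 0.39 (adjusted p = 4.3e-14). TSC22D3, a glucocorticoid-induced regulator, fell by 6.21 ± 0.42. NMRAL1, RPP25, TNNI3, HOXC10 and DPYSL4 were lower by between 3.41 and 4.84, with -4.84 ± 0.44 for NMRAL1 and -3.41 ± 0.49 for HOXC10. The size for HOXC10 is uncertain, since its untreated RPS26dC Input libraries had 4.91 and 0.923 CPM.

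Some targets of ATF4 and some cholesterol synthesis genes were lower in untreated RPS26dC cells. Of 35 targets of this transcription factor of the integrated stress response, 8 fell and none rose, 11 and 0 when adjusted over the list alone. Among them were CHAC1 (-3.38 ± 0.49), DDIT4, an inhibitor of mTOR complex 1 signalling (-3.13 ± 0.32), ATF4 itself (-1.35 ± 0.19), TRIB3 (-1.74 ± 0.27), SESN2 (-1.83 ± 0.41) and DDIT3 (-0.80 ± 0.22). The list median was -0.54 (camera adjusted p = 1e-06, and adjusted p = 0.13 with an estimated correlation). SESN2 is among the genes that also differed between the RPS26dC numbers. Of 25 cholesterol synthesis genes, 7 fell (8 adjusted over the list alone), with IDI1 at -1.94 ± 0.26, MVD at -1.71 ± 0.33, HSD17B7 at -1.62 ± 0.29 and NSDHL at -1.35 ± 0.25. The list median was -0.35 (adjusted p = 0.00096, and adjusted p = 0.14 with an estimated correlation). Of 23 immediate early genes, 6 rose and 1 fell, counts that were unchanged when adjusted over the list alone, with CCN1 at 1.88 ± 0.39 and a list median of 0.57 (adjusted p = 0.00096, and adjusted p = 0.14 with an estimated correlation). Of 13 neuronal-lineage genes that HEK293 cells express, 4 rose (NEFM, NEFL, GATA2 at 1.53 ± 0.21, GAP43 at 1.74 ± 0.43) and 1 fell (4 and 2 adjusted over the list alone). Their median was 0.10, between -0.07 and 0.30 when any 1 library was left out, and their mean 0.87 (adjusted p = 1.2e-05, and adjusted p = 0.012 with an estimated correlation). Without the RPS26dC libraries numbered 1 the list did not pass (adjusted p = 0.055). Ribosomal protein mRNAs did not pass as a list of 78 (median -0.08, adjusted p = 0.19), while 7 single members fell, 6 adjusted over the list alone, RPS6 among them at -1.08 ± 0.18. VEGFA was lower by 0.88 on the log2 scale, at -0.88 ± 0.24, and the chaperone HSPA5 differed by 0.03 ± 0.29 (adjusted p = 0.97).

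Markers of other cell types were followed as well. Of 6 measured epithelial markers, KRT17 was higher at 13.3 ± 6.53 against 0.373 ± 0.528 CPM and ITGB4 lower, with 0 counts in untreated RPS26dC against 2.56 ± 0.72 CPM in WT, at least 10.5-fold lower against a floor of 3 counts over the group. The list did not pass (adjusted p = 0.23, with 1 higher and 1 lower also when adjusted over the list alone). Of 6 measured fibroblast markers, 1 was higher, also when adjusted over the list alone: COL3A1, at 7.95 ± 6.54 against 0.283 ± 0.128 CPM, and the list did not pass (adjusted p = 0.34).

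In all, 926 genes were higher and 800 lower in untreated RPS26dC Input (edgeR, 12.4% of those tested). A control for the correction below, which subtracted the medians of neighbouring genes in shuffled order, kept 1470 of the 1726 called. Leaving out any 1 of the 4 libraries gave 761 to 934 genes in total, and after subtracting the median change of neighbouring genes, which removes what whole chromosome segments share, 728 of the 1726 were still called (849 called in total), with DDIT3 not among them, IDI1 at -1.20 and RPS6 at -0.62. The subtracted medians ran from -0.74 (IDI1) to -0.28 (NSDHL) in the cholesterol synthesis genes named above. In the ATF4 targets named above they ran from -0.53 (DDIT3) to 0.09 (CHAC1). The list tests were not repeated after this correction, so how much of the list shifts whole segments share was not tested. Among the 36 named genes that passed, 29 also did without each library in turn.

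Starvation left the genotype difference in place. In starved Input, 957 genes were higher and 850 lower in RPS26dC, and 579 and 484 of these were called in the same direction in untreated cells, against 63.8 and 49 for unrelated sets and 0 called in opposite directions. NEFM (5.2 ± 0.20), NEFL (4.07 ± 0.22), TNC (6.27 ± 0.44), CCN3 (5.57 ± 0.29), CD44 (5.22 ± 0.40), KLF4 (4.55 ± 0.35), MYC (2.59 ± 0.26) and CCN1 (2.94 ± 0.39) were again higher. So were the membrane-associated neuronal gene BASP1 (5.38 ± 0.57) and SGCE (5.29 ± 0.37), the imprinted neighbour of PEG10 on chromosome 7. IRS4 (-7.84 ± 0.37), TSC22D3 (-6.34 ± 0.41), RPP25 (-3.87 ± 0.30) and the homeobox genes HOXA6 (-5.54 ± 0.38) and HOXA13 (-3.72 ± 0.40) were lower, and RPS6 was lower again (-1.16 ± 0.18). The 13 neuronal-lineage genes had 4 higher and 2 lower (4 and 3 adjusted over the list alone), with GATA2 at 1.62 ± 0.21 and GAP43 at 2.46 ± 0.46. Their median was 0.49 (adjusted p = 3.1e-05, and adjusted p = 0.012 with an estimated correlation).

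Some ATF4 targets, chaperones of the endoplasmic reticulum (ER) and heat shock genes were lower in starved RPS26dC cells. Of 35 ATF4 targets, 15 were lower and 0 higher (22 and 0 adjusted over the list alone), with a list median of -0.80 (adjusted p = 4.3e-11, and adjusted p = 0.016 with an estimated correlation). TRIB3 (-3.04 ± 0.28), DDIT4 (-2.23 ± 0.29), SESN2 (-1.94 ± 0.41), DDIT3 (-1.52 ± 0.22) and ATF4 (-0.80 ± 0.19) were among them. Of 30 chaperones and degradation factors of the ER, 10 were lower (15 adjusted over the list alone), and the list median was -0.56 (adjusted p = 1.9e-08, and adjusted p = 0.012 with an estimated correlation). HSPA5, the main ER chaperone (ENSG00000044574, chromosome 9, 125234853 to 125241330), stood at 630 ± 186 CPM in starved WT and 228 ± 80.2 in starved RPS26dC (SD, n = 2), a difference of -1.47 ± 0.29 (adjusted p = 0.0012). HERPUD1 (-2.20 ± 0.33), PDIA4 (-1.56 ± 0.22), P4HB (-1.39 ± 0.21) and XBP1 (-1.27 ± 0.19) were lower as well. Of 18 cytosolic heat shock genes, 6 were lower and 1 higher (7 and 1 adjusted over the list alone), with DNAJB1 at -1.51 ± 0.25, HSPA8 at -1.28 ± 0.30, HSPA1B at -1.79 ± 0.31 and HSPA1A, its near-identical neighbour, at 7.02 ± 0.57. That list's median was -0.59 (adjusted p = 0.026, and adjusted p = 0.29 with an estimated correlation). Of 25 cholesterol synthesis genes, 6 were lower (8 adjusted over the list alone), IDI1 at -1.58 ± 0.26, with a median of -0.15 (adjusted p = 0.023, and adjusted p = 0.29 with an estimated correlation). KRT17 stood at 18.7 ± 1.23 CPM against 0 counts in WT, at least 56.7-fold higher. ITGB4 was at least 9.73-fold lower, and COL1A1 was higher by 1.41 ± 0.42. Neither the epithelial (adjusted p = 0.11, 4 higher and 1 lower adjusted over the list alone) nor the fibroblast list (adjusted p = 0.32, 2 higher adjusted over the list alone) passed.

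The starved comparison called 1807 genes, and 1531 of them stayed called after the control that subtracted shuffled medians. Leaving out any 1 of its 4 libraries gave 941 to 1179, and after subtracting the median change of neighbouring genes 894 of the 1807 were still called (1043 called in total), with ATF4, P4HB and IDI1 not among them and RPS6 at -0.68. The subtracted medians ran from -0.91 (P4HB) to 0.1 (HSPA5) in the ER genes named above. In the ATF4 targets named above they ran from -0.47 (ATF4) to -0.11 (DDIT4). The list tests were not repeated after the correction here either. Without 1 of the 4 libraries HSPA8 lay between -1.93 and -0.85 and did not pass in 2 of 4 cases (adjusted p up to 0.13), its starved RPS26dC libraries having 170 and 359 CPM.

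**Figure D1:**
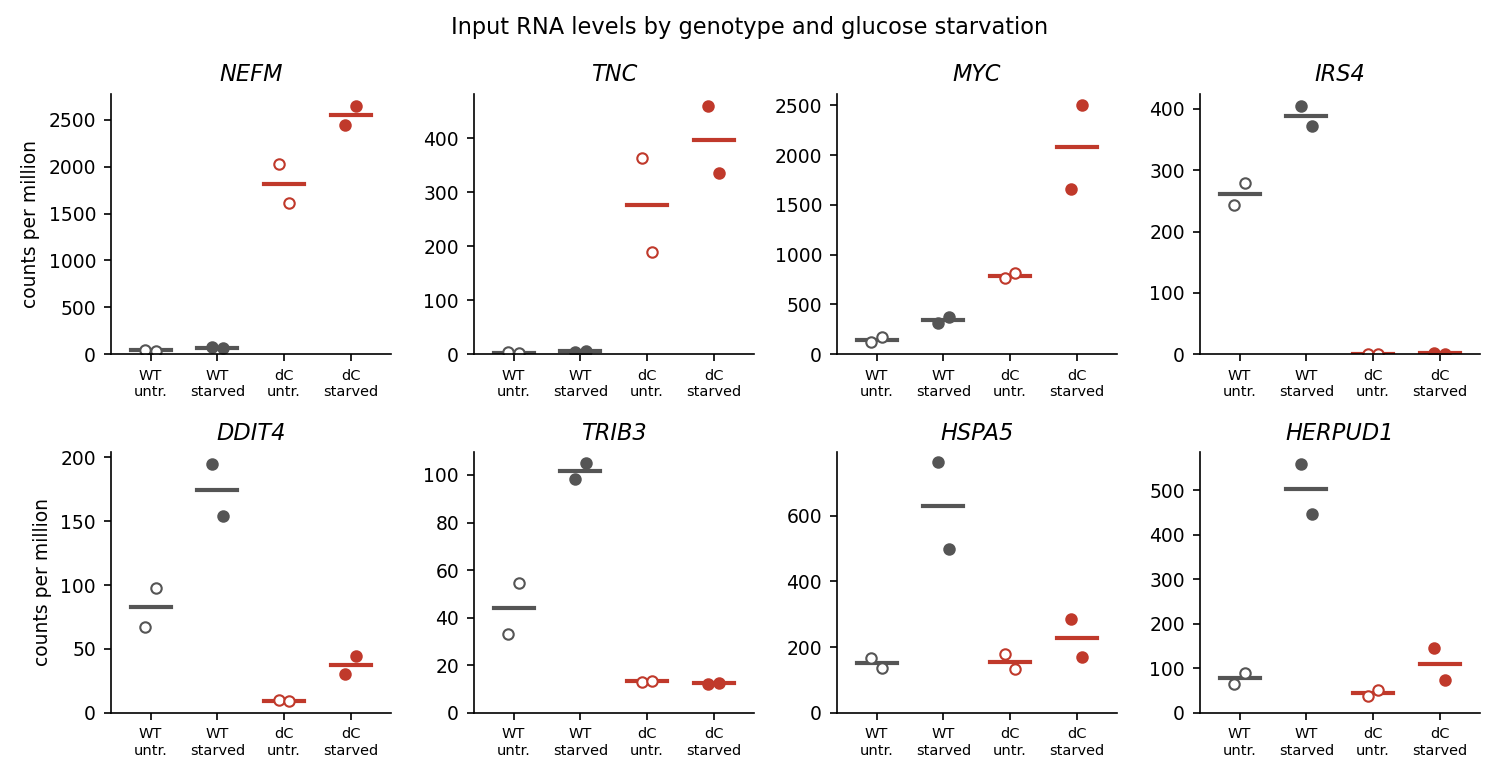
Normalised level in CPM of 8 genes, each on its own linear axis, in each Input library of WT and RPS26dC, untreated (open) and starved (filled), with the mean of each group of 2 libraries. NEFM, TNC and MYC lie higher and IRS4, DDIT4 and TRIB3 lower in RPS26dC in both conditions, and HSPA5 reaches 630 CPM on average in starved WT against 228 in starved RPS26dC.

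ER stress, ATF4 and immediate early transcripts were higher in Input of starved than of untreated WT cells. The starvation medium also held dialysed serum, and no group had that serum with glucose, so the 2 cannot be told apart. HERPUD1, an ER-associated degradation factor, rose by 2.70 ± 0.33 (adjusted p = 0.00021), from 77.5 ± 17.7 to 503 ± 81.1 CPM (SD, n = 2), HSPA5 by 2.05 ± 0.30 and XBP1, a transcription factor of the unfolded protein response, by 1.12 ± 0.19. These were the 3 of 30 ER list members that passed (13 adjusted over the list alone), 28 of the 30 lay above 0, and the list rose with a median of 0.48 (adjusted p = 5.5e-18, and adjusted p = 0.00056 with an estimated correlation). Of 35 ATF4 targets, 5 rose (13 adjusted over the list alone): DDIT3 (1.53 ± 0.22), ATF3 (2.31 ± 0.45), CEBPB (1.18 ± 0.21), CTH (1.78 ± 0.36) and TRIB3 (1.21 ± 0.26). Their list had a median of 0.64 (adjusted p = 1.3e-21, and adjusted p = 0.00094 with an estimated correlation). Of 23 immediate early genes, 6 rose (11 adjusted over the list alone): ATF3 again, EGR1 (2.82 ± 0.41), FOS (2.92 ± 0.52), FOSB (3.26 ± 0.62), JUN (1.45 ± 0.29) and MYC (1.23 ± 0.25). The immediate early list had a median of 1.03 (adjusted p = 2.2e-18, and adjusted p = 0.00056 with an estimated correlation). The polyamine enzyme gene SAT1 (1.30 ± 0.26), ZBTB21 (1.70 ± 0.34) and IQCB1 (1.22 ± 0.23) completed the 16 genes that rose, and EXTL3 (-1.43 ± 0.24), SALL2 (-1.47 ± 0.31) and PHF23 (-1.01 ± 0.20) were the 3 that fell. DDIT4 differed by 1.08 ± 0.28 (adjusted p = 0.16).

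Other lists moved little in starved WT Input. The 78 ribosomal protein mRNAs had a median of 0.23 with 70 above 0 and none passing singly, adjusted over the list alone or over all genes (adjusted p = 1.9e-07, and adjusted p = 0.4 with an estimated correlation). The 30 genes of G2 and mitosis had a median of -0.24, with none passing in either count (adjusted p = 0.0071, and adjusted p = 0.54 with an estimated correlation), and of between -0.50 and 0.01 when any 1 library was left out. The 7 measured targets of the glucose sensors MondoA and ChREBP did not pass (median 0.15, adjusted p = 0.33), nor did any member, in either count. The 19 calls were edgeR's with the pooled spread. DESeq2 called 52, the fit to the compared groups alone 76, and leaving out any 1 of the 4 libraries left 0 to 8.

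In RPS26dC Input, starvation raised ATF4 targets and immediate early genes. CHAC1, a glutathione-degrading ATF4 target, rose by 2.94 ± 0.49 (adjusted p = 0.0081), DDIT4 by 1.98 ± 0.32 and the secreted stanniocalcin gene STC2 by 1.60 ± 0.31, the 3 of 35 ATF4 targets that passed (8 adjusted over the list alone). The ATF4 target list had a median of 0.35 (adjusted p = 1e-10, and adjusted p = 0.029 with an estimated correlation). CCN1 rose by 2.77 ± 0.38 and MYC by 1.39 ± 0.25, the 2 of 23 immediate early genes that passed (11 higher and 1 lower adjusted over the list alone). That list had a median of 0.54 (adjusted p = 2.6e-12, and adjusted p = 0.0061 with an estimated correlation). FOS and ATF3 had values of 2.45 ± 0.53 and 2.07 ± 0.44 (adjusted p = 0.069 each). The proapoptotic BH3-only gene PMAIP1 (1.34 ± 0.26) and the inhibitors of differentiation ID2 (1.02 ± 0.21) and ID4 (1.35 ± 0.27) also rose. ZC3HAV1, an antiviral zinc finger gene (-2.12 ± 0.35), RBM14 (-1.51 ± 0.24) and PNMA8A (-1.34 ± 0.27) fell. ER chaperones did not pass as a list (median 0.05, adjusted p = 0.24, with 0 members passing and 2 adjusted over the list alone). Without the RPS26dC libraries numbered 1 the median of that list was -0.03, so its sign depended on the number. HSPA5 stood at 0.55 ± 0.29 (adjusted p = 0.8) and DDIT3 at 0.82 ± 0.22 (adjusted p = 0.21). Ribosomal protein mRNAs had a median of 0.21 (adjusted p = 4.9e-06, and adjusted p = 0.52 with an estimated correlation). Genes of G2 and mitosis had a median of -0.16 (adjusted p = 0.017, and adjusted p = 0.56 with an estimated correlation), and the 7 MondoA and ChREBP targets a median of 0.00 (adjusted p = 0.63). No member of these 3 lists passed in either count. The 9 genes higher and 5 lower were counted in the presence of the difference between numbers 1 and 2, which takes in ATF3 and SESN2. The main fit held no term for that difference, and fits with such a term called more genes, as given under the dependence on processing. DESeq2 called 51, the fit to the compared groups alone 2, RPS26dC numbered 2 alone 52 and numbered 1 alone 5, and leaving out any 1 of the 4 libraries gave 0 to 17.

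Set against each other, the Input responses shared 1 gene, MYC, and correlated with Pearson's r of 0.36 over 7916 genes. The test of the difference in response called 0 genes with edgeR (587 at an unadjusted p under 0.05) and 0 with DESeq2. Among lists, ER chaperones responded less in RPS26dC, with a median difference of -0.41 and 28 of 30 members below 0 (adjusted p = 8e-09, and adjusted p = 0.017 with an estimated correlation). No single member passed (2 adjusted over the list alone), with values of -1.50 ± 0.41 for HSPA5, -1.56 ± 0.39 for SDF2L1 and -1.39 ± 0.45 for HERPUD1. Without a count filter 3 genes were called, and without the RPS26dC libraries numbered 1, an analysis added after the data were seen, 2.

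Untreated WT cells showed where mRNAs sat on polysomes in fed cells. Against Light, Heavy was richer in the messages of glycolytic enzymes such as PGK1 (3.07 ± 0.19), PKM (2.89 ± 0.25), ALDOA (1.94 ± 0.17) and GAPDH (1.48 ± 0.17), and of replication factors such as PCNA (3.09 ± 0.25) and MCM5 (2.72 ± 0.21). ACTB (2.29 ± 0.18) and the lamin gene LMNA (3.11 ± 0.23) were richer there too, with the ER proteins PDIA3 (3.29 ± 0.28) and HSPA5 (2.30 ± 0.31), the RNA-binding proteins EIF4A3 (3.46 ± 0.22) and HNRNPA2B1 (3.13 ± 0.19) and MAGED1 (3.09 ± 0.19). Light was richer in short messages such as those of the ribosomal proteins RPS21 (-2.38 ± 0.21) and RPL36 (-1.76 ± 0.16) and the respiratory subunits UQCRQ (-2.53 ± 0.19) and UQCR11 (-2.68 ± 0.20). It was also richer in COX14 (-2.79 ± 0.24), COMMD6 (-3.03 ± 0.33) and the copper chaperone ATOX1 (-2.75 ± 0.27), and in ATF4 (-1.42 ± 0.19), whose upstream open reading frames limit its translation in unstressed cells. SDHA, a large respiratory subunit, went the other way from its list (2.85 ± 0.21). In total 3091 genes were higher in Heavy and 2908 in Light.

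By list, 19 of 24 glycolysis genes were higher in Heavy than in Light (20 adjusted over the list alone, median 1.65, adjusted p = 2.6e-12, and adjusted p = 0.0082 with an estimated correlation). Of 30 replication genes, 22 were higher and 2 lower, in both counts adjusted over the list alone too (median 1.12, adjusted p = 1.4e-10, and adjusted p = 0.025 with an estimated correlation). Of 77 nuclear-encoded respiratory genes, 12 were higher and 55 lower (12 and 56 adjusted over the list alone, median -1.28, adjusted p = 1.5e-11, and adjusted p = 0.025 with an estimated correlation). Of 78 ribosomal protein mRNAs, 2 were higher and 56 lower (2 and 58 adjusted over the list alone, median -1.18, adjusted p = 6.7e-14, and adjusted p = 0.1 with an estimated correlation).

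Against Input, Heavy of untreated WT was poorer in the ferritin messages FTL (-1.98 ± 0.21) and FTH1 (-1.87 ± 0.29), whose translation iron regulates, and OST4 (-1.87 ± 0.20). It was also poorer in the ribosomal proteins RPS12 (-1.78 ± 0.23), RPLP1 (-1.33 ± 0.16), RPLP2 (-1.29 ± 0.16) and RPS6 (-0.77 ± 0.18), the respiratory subunits COX8A (-1.41 ± 0.19) and UQCR11 (-1.43 ± 0.19), COMMD6 (-1.99 ± 0.33) and CAD (-1.78 ± 0.24), the large enzyme of pyrimidine synthesis. FTH1 and OST4 had nearly the same counts as the overlapping genes BEST1 and AGBL5. Higher in Heavy were HMOX1 (1.24 ± 0.31), NECTIN3 (1.30 ± 0.37), PRNP (1.07 ± 0.28), VAT1 (1.05 ± 0.25), ACTB (0.77 ± 0.18), PGK1 (0.76 ± 0.17) and ALDOA (0.64 ± 0.17). Of the ribosomal protein mRNAs, 42 of 78 were lower (56 adjusted over the list alone, median -0.81, adjusted p = 7.2e-30, and adjusted p = 0.09 with an estimated correlation). Of the respiratory genes, 22 of 77 were lower (25 lower and 6 higher adjusted over the list alone, median -0.40, adjusted p = 2.2e-05, and adjusted p = 0.28 with an estimated correlation). Glycolysis genes had 2 of 24 higher (4 adjusted over the list alone, median 0.48, adjusted p = 4.2e-05, and adjusted p = 0.12 with an estimated correlation). The test called 198 higher and 716 lower, and leaving out any 1 of the 4 libraries left 160 to 391, against 2200 from the fit to these groups alone.

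Starvation lowered ribosomal protein mRNAs in Heavy relative to Input in both genotypes. In WT, RPL29 (-1.33 ± 0.23), RPS3 (-1.32 ± 0.24) and RPL14 (-1.22 ± 0.22) fell (adjusted p = 0.027 each). The median of the 78 was -0.75 with 75 members below 0, and 45 passed when adjusted over the list alone (camera adjusted p = 3.5e-48, and adjusted p = 0.014 with an estimated correlation). RPL14 (ENSG00000188846, chromosome 3, 40457292 to 40468587) went from 2020 ± 97 to 1030 ± 32.2 CPM in Heavy while Input held 1970 ± 130 and 2330 ± 114 (SD, n = 2). The adenine nucleotide carrier SLC25A6 fell with them (-1.37 ± 0.25), and 2 messages with long coding sequences rose, CAD (1.75 ± 0.34) and the spliceosome scaffold PRPF8 (1.75 ± 0.31). Other mRNAs with a 5' terminal oligopyrimidine tract, which mTOR controls, had none of 22 passing and 4 adjusted over the list alone (median -0.49, adjusted p = 1e-09, and adjusted p = 0.1 with an estimated correlation). Respiratory genes (median -0.25, adjusted p = 8.6e-06, and adjusted p = 0.19 with an estimated correlation) and mitochondrial ribosomal proteins (median -0.27, adjusted p = 0.00014, and adjusted p = 0.69 with an estimated correlation) had no member passing in either count. ATF4 had a value of 0.33 ± 0.27 (adjusted p = 1).

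In RPS26dC the same ratio fell for 11 of 78 ribosomal protein mRNAs (53 adjusted over the list alone, median -0.84, adjusted p = 5.9e-58, and adjusted p = 0.0067 with an estimated correlation). They included RPL24 (-1.62 ± 0.31), RPL7A (-1.43 ± 0.24), RPL14 (-1.36 ± 0.22), RPL15 (-1.29 ± 0.25) and RPS19 (-1.18 ± 0.22). RACK1, a ribosomal scaffold protein (-1 ± 0.20), was the 1 of 22 other oligopyrimidine mRNAs that fell (14 adjusted over the list alone, median -0.92, adjusted p = 3.5e-17, and adjusted p = 0.015 with an estimated correlation). GAPDH fell by 1.20, at -1.20 ± 0.24. Rising messages were RRBP1 (1.90 ± 0.40), CKAP5 (1.77 ± 0.36), CAD (1.74 ± 0.33), and GTF3C1 (1.57 ± 0.34). Also rising were the nuclear pore protein TPR (1.50 ± 0.30), PRPF8 (1.46 ± 0.31), the DNA repair kinase PRKDC (1.41 ± 0.28), the tRNA synthetase EPRS1 (1.24 ± 0.26) and ATF4 (1.33 ± 0.27). Respiratory genes fell as a list (median -0.36, adjusted p = 1.1e-11, and adjusted p = 0.032 with an estimated correlation) with 0 members passing, 2 adjusted over the list alone and ATP5PO at -1.07 ± 0.24 (adjusted p = 0.059). Mitochondrial ribosomal proteins (median -0.33, adjusted p = 6.6e-10, and adjusted p = 0.28 with an estimated correlation) and the proteasome (median -0.38, adjusted p = 5.2e-05, and adjusted p = 0.53 with an estimated correlation) had no member passing in either count.

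These ratios called 2 higher and 4 lower in WT and 11 and 13 in RPS26dC, with 2 and 3 shared. Without a spread pooled over the genotypes, in the fit to the compared groups alone, the order of the genotypes turned (92 and 0). That fit held no term for the difference between numbers 1 and 2. With such a term within each genotype, added after the data were seen, more genes were called in RPS26dC than in WT. The split in RPS26dC was 19 and 7 with library totals and 7 and 13 with relative log expression, that in WT 1 and 4 with the latter. Scaling by library totals moved the median of all genes by 0.11 in WT and 0.16 in RPS26dC, and the ribosomal protein medians were then -0.63 and -0.69. DESeq2 called 56 and 95, the fit to the compared groups alone 92 and 0, and leaving out any 1 of the 8 libraries gave 0 to 1 and 0 to 28. With Light in place of Heavy 36 and 9 were called, and GAPDH (0.83), RACK1 (0.33) and ATF4 (-0.48) in RPS26dC lay on the other side of 0.

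**Figure D2:**
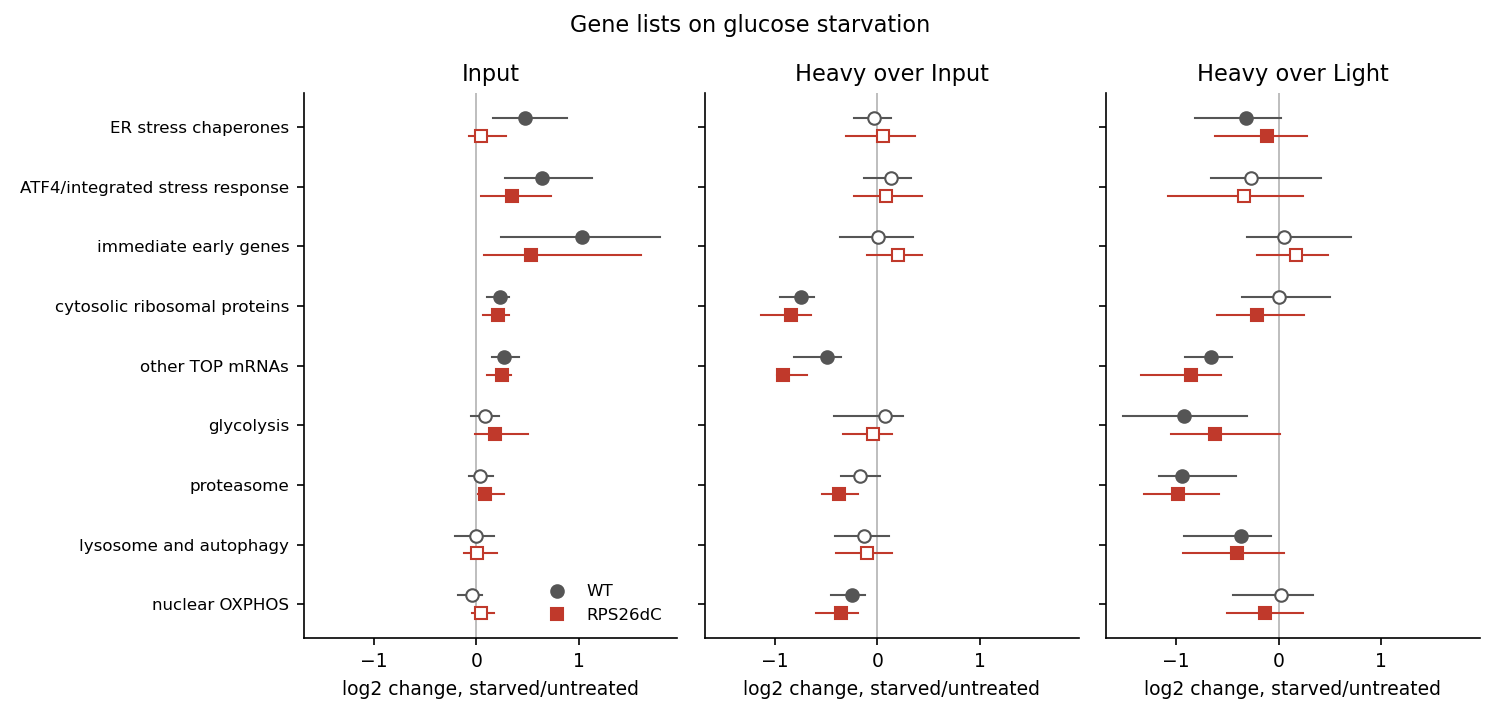
Median log2 change on starvation of 9 gene lists (points) with the quartiles of their members (bars), in WT and RPS26dC, filled where the list passed camera with its preset correlation and open where it did not. The ribosomal protein list lies at -0.75 in WT and -0.84 in RPS26dC for Heavy over Input.

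Within the polysomes, starvation lowered the Heavy over Light ratio of glycolysis and cytoskeleton mRNAs in WT, relative to other mRNAs. Since equal amounts of RNA were sequenced, a movement of the bulk of mRNA between the fractions would not be seen. GAPDH (ENSG00000111640, chromosome 12, 6533927 to 6538374) went from 2340 ± 54.3 to 1340 ± 36.5 CPM in Heavy and from 842 ± 4.43 to 1500 ± 128 in Light (SD, n = 2). Its Heavy over Light ratio changed by -1.64 ± 0.24 (adjusted p = 0.0014). ACTB (-1.80 ± 0.25), ALDOA (-1.52 ± 0.24), LDHA (-1.85 ± 0.39), PGK1 (-1.14 ± 0.25), the intermediate filament VIM (-1.75 ± 0.35), and the actin-binding CNN3 (-1.80 ± 0.35) fell too. So did the ATP synthase subunit ATP5F1B (-1.75 ± 0.29), the ER enzyme PDIA3 (-1.82 ± 0.37), the mitotic activator CDC20 (-1.74 ± 0.36), the G protein GNAI3 (-1.94 ± 0.40) and the splicing factor SNRNP40 (-2.23 ± 0.49). HS3ST3A1 (1.68 ± 0.36) and CAD (1.44 ± 0.34) rose, as did TNC (3.51 ± 0.83), which was scarce in WT polysomes at 1.29 ± 0.779 CPM in untreated and 3.09 ± 2.33 in starved Heavy, and 4.66 ± 1.43 and 1.13 ± 0.551 in Light (SD, n = 2). ATF4 had a value of 0.85 ± 0.27 (adjusted p = 0.14).

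Of 24 glycolysis genes, 5 fell in WT (10 adjusted over the list alone), with a list median of -0.92 (adjusted p = 9.2e-12, and adjusted p = 0.0085 with an estimated correlation). The proteasome had 2 of 35 falling, PSMC4 at -1.84 ± 0.44 among them (19 adjusted over the list alone, median -0.94, adjusted p = 1.9e-13, and adjusted p = 0.068 with an estimated correlation). Lysosome and autophagy genes had 3 of 65, with PSAP at -1.45 ± 0.28 and the protease CTSD at -1.29 ± 0.30 (16 lower and 2 higher adjusted over the list alone, median -0.37, adjusted p = 1.3e-06, and adjusted p = 0.064 with an estimated correlation). The citric acid cycle had 1 of 27 (10 adjusted over the list alone, median -0.64, adjusted p = 3.1e-06, and adjusted p = 0.064 with an estimated correlation). The other oligopyrimidine mRNAs had 2 of 22 falling (10 adjusted over the list alone, median -0.66, adjusted p = 6e-08, and adjusted p = 0.064 with an estimated correlation). Ribosomal protein mRNAs did not pass in this ratio (median 0.00, adjusted p = 0.97), with 0 of 78 members passing and 1 higher and 7 lower adjusted over the list alone. Totals were 7 genes higher and 88 lower. DESeq2 called 435, library totals 171, relative log expression 53, no filter 292 and the fit to the compared groups alone 436, and leaving out any 1 of the 8 libraries left 6 to 31, with ACTB, ALDOA and GAPDH called each time.

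In RPS26dC cells the Heavy over Light ratio changed for many of the same mRNAs. In all, 60 of the genes that fell and 1 that rose were shared, against 1.77 and 0.0192 for unrelated sets. Changes correlated with Pearson's r of 0.70 over 7916 genes. GAPDH (-2.03 ± 0.24, adjusted p = 6.6e-05), ALDOA (-1.66 ± 0.24), LDHA (-2.15 ± 0.39), PGK1 (-0.99 ± 0.25) and ATP5F1B (-1.78 ± 0.29) fell again. Lower too were ACTG1 (-1.81 ± 0.24), RACK1 (-1.33 ± 0.20), the initiation factor subunit EIF3H (-1.50 ± 0.28), HNRNPA1 (-1.43 ± 0.27) and RPL6 (-1.85 ± 0.34). SLC25A5 (-1.87 ± 0.33), AHCY (-1.83 ± 0.31), the proteasome subunit PSMB7 (-1.77 ± 0.35) and the lysosomal GUSB (-1.85 ± 0.27), CTSD (-1.74 ± 0.30) and PSAP (-1.52 ± 0.28) fell as well. ATF4 rose in this ratio by 1.81 ± 0.27 (adjusted p = 0.00069), along with AZIN1 (1.61 ± 0.34) and IFRD1 (1.53 ± 0.34), which also carry upstream reading frames. PNRC2 (1.98 ± 0.40), the RNA polymerase subunit POLR2A (2.02 ± 0.49), ESPL1 (1.65 ± 0.39), TRRAP (1.63 ± 0.36) and the talin TLN1 (1.58 ± 0.35) rose as well.

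Of 24 glycolysis genes, 6 fell in RPS26dC (9 adjusted over the list alone, median -0.62, adjusted p = 2e-06, and adjusted p = 0.037 with an estimated correlation). The other oligopyrimidine mRNAs had 8 of 22 falling (14 adjusted over the list alone, median -0.86, adjusted p = 5.5e-14, and adjusted p = 0.037 with an estimated correlation). Lysosome and autophagy genes had 11 of 65 falling (15 adjusted over the list alone, median -0.41, adjusted p = 3e-07, and adjusted p = 0.037 with an estimated correlation). The proteasome had 9 of 35 (22 adjusted over the list alone, median -0.98, adjusted p = 4.2e-14, and adjusted p = 0.082 with an estimated correlation). The citric acid cycle had 6 of 27 falling (11 lower and 1 higher adjusted over the list alone, median -0.71, adjusted p = 4.5e-06, and adjusted p = 0.079 with an estimated correlation). Of 78 ribosomal protein mRNAs, 6 fell (2 higher and 15 lower adjusted over the list alone, median -0.21, adjusted p = 0.0058, and adjusted p = 0.51 with an estimated correlation). Totals were 38 genes higher and 279 lower, in libraries whose numbers 1 and 2 differed as described. Without a spread pooled over the genotypes, in the fit to the compared groups alone, fewer genes were called here than in WT. That fit held no term for the difference between the numbers. With such a term within each genotype, added after the data were seen, more genes were called here than in WT, as given under the dependence on processing. DESeq2 called 785, no filter 550 and the fit to the compared groups alone 0, RPS26dC numbered 2 alone gave 560 and numbered 1 alone 63, and leaving out any 1 of the 8 libraries gave 41 to 607.

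The comparison at the centre of the design asks whether losing the RPS26 tail changes which mRNAs are on heavy polysomes beyond the change in total mRNA. For Heavy over Input, edgeR called 0 genes in untreated cells (517 at an unadjusted p under 0.05) and 0 in starved cells (482), and DESeq2 called 0 in both. The test of the difference between genotypes in the starvation response of this ratio called 0 genes too (436 at an unadjusted p under 0.05, and 0 in DESeq2). Its median standard error was 0.51 over genes averaging at least 4 log2 CPM. In the response difference, ATF4 had a value of 1.00 ± 0.38 (adjusted p = 1), and the ribosomal protein list a median of -0.13 (adjusted p = 0.2). Ribosomal protein mRNAs lay higher in RPS26dC in untreated cells, with a median of 0.30, 68 of 78 above 0 and none passing in either count (adjusted p = 6.8e-08, and adjusted p = 0.87 with an estimated correlation). The median without the RPS26dC libraries numbered 2 was 0.14. In starved cells their median was 0.19 (adjusted p = 0.045, and adjusted p = 0.97 with an estimated correlation). The other oligopyrimidine mRNAs had a median of 0.27 in untreated cells, none passing in either count (adjusted p = 0.033, and adjusted p = 0.87 with an estimated correlation). The 34 genes of AMPK and mTOR signalling, the pathways named in the study's title, did not pass, with medians of 0.09 (adjusted p = 0.91) in untreated and 0.02 (adjusted p = 0.91) in starved cells and 0 members called in either count.

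For Heavy over Light, the matrix protein gene CCN3 (ENSG00000136999, chromosome 8, 119416306 to 119424353) was the single gene called in untreated cells, higher in RPS26dC by 2.46 ± 0.38 (adjusted p = 0.0089). Its Heavy level was 839 ± 89.8 CPM and its Light level 231 ± 21.2 in RPS26dC, against 6.01 ± 0.17 and 9.15 ± 2.36 in WT (SD, n = 2). In starved cells edgeR called 0 (568 at an unadjusted p under 0.05) and DESeq2 4. Ribosomal protein mRNAs had a median of 0.29 in untreated cells with none passing in either count (adjusted p = 1.2e-06, and adjusted p = 1 with an estimated correlation). The other oligopyrimidine mRNAs had 0.56, with 0 passing and 10 adjusted over the list alone (adjusted p = 2e-09, and adjusted p = 0.22 with an estimated correlation). For untreated cells DESeq2 called 20, no filter 25 and RPS26dC numbered 2 alone 49, and leaving out any 1 of the 8 libraries gave 0 to 2.

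Coding length separated messages in the polysome fractions. In untreated WT, the median Heavy over Light ratio rose from -2.02 for coding sequences under 300 nucleotides to 0.62 for those of 1500 to 3000, and was 0.32 for those of 6000 or more. The starvation change in Heavy over Input ran from -0.02 to 0.39 in WT and from -0.06 to 0.52 in RPS26dC between the same ends, with lowest medians of -0.17 and -0.20 at 600 to 900 nucleotides. Across 7807 genes, which are not independent replicates, this change had a Spearman correlation with coding length of 0.29 in WT and 0.33 in RPS26dC. In Heavy over Light the starvation change was positive at both ends. Its medians in WT and RPS26dC were 0.45 and 0.43 under 300 nucleotides, and 0.30 and 0.59 at 6000 or more. They were lowest, at -0.22 and -0.21, for 900 to 1500 nucleotides.

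**Figure D3:**
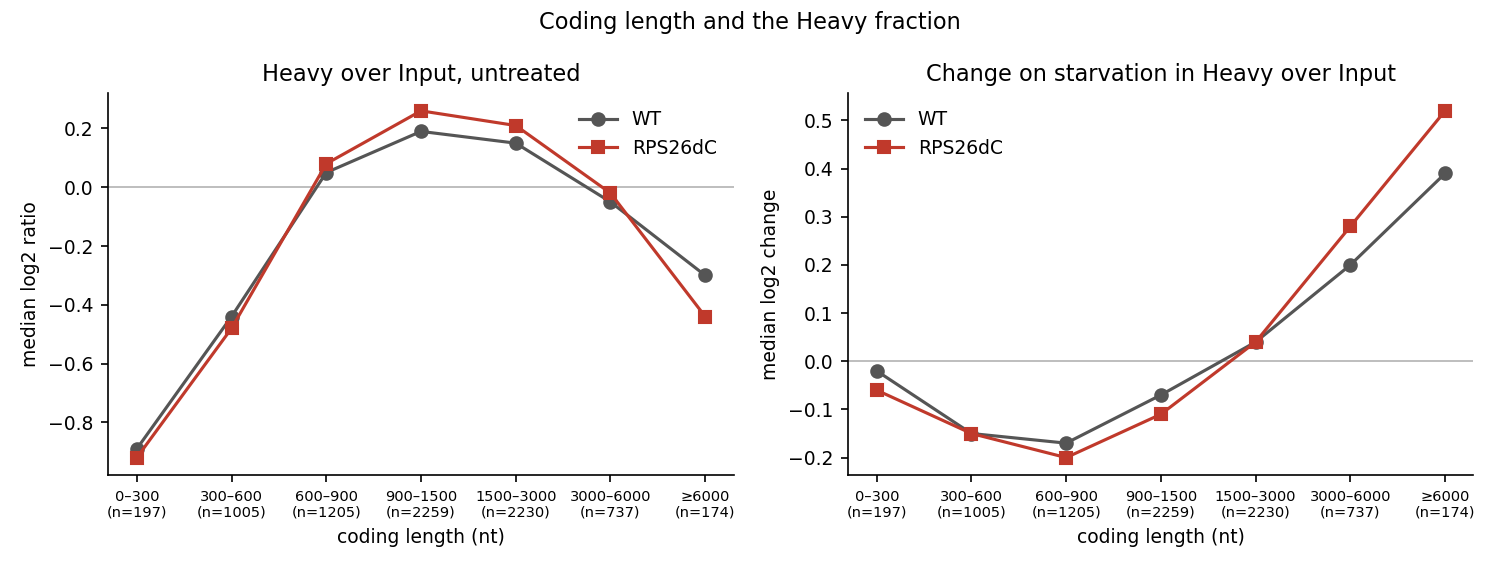
Median log2 ratio or starvation change (vertical axis) of genes grouped by coding length in nucleotides (horizontal axis), in WT and RPS26dC. The left panel shows Heavy over Input in untreated cells, which in WT is -0.89 for the shortest group, 0.19 for 900 to 1500 nucleotides and -0.30 for the longest. The right panel shows the change in Heavy over Input on starvation, which is highest, at 0.39 in WT and 0.52 in RPS26dC, for coding sequences of 6000 nucleotides or more.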

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

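The difference between the genotypes in how ER chaperone mRNAs answered starvation was singled out by its own test. The median difference in response was -0.41 (camera adjusted p = 8e-09, and adjusted p = 0.017 with an estimated correlation). The other results here were singled out because all libraries of one group moved one way and all of the other the opposite way. For those in Input and in Heavy over Input the test of the response difference called 0 genes, and for those in Heavy over Light the difference was not tested. On starvation in Input, WT and RPS26dC had changes of 1.21 and -0.09 for TRIB3, 0.55 and -1.62 for HOXA6, 1.13 and -0.43 for SDF2L1, and 0.74 and -0.34 for DNAJC3. For RPS26dC against WT in Input, untreated and starved cells had -0.48 and 0.45 for SALL2 and 0.45 and -0.85 for ZC3HAV1. In Heavy over Input the genotype differences were -0.53 and 0.48 for ATF4 and -0.38 and 0.29 for PRKDC. In Heavy over Light, starvation changed CCN3 by 0.58 in WT and -1.20 in RPS26dC, and the genotype differences in untreated and starved cells were -0.53 and 0.60 for SNRNP40 and -0.41 and 0.71 for PNRC2. These are 11 of 264 gene comparisons, where unrelated groups would give 14.7.

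For the patterns weighed below and in the last part, the tests of depth, 3' UTR length and short coding sequences were written before their values were seen. The tests of copy number, WT admixture, fibroblast RNA and loss of the longest mRNAs were written or changed after earlier values. Copy number between the RPS26dC numbers had left the question undecided by its most extreme window of neighbouring genes (0.21), and the genotype test, which had counted all called genes (849 called after correction against 1726), was split at 4-fold, where a version by calls kept (78%, and 96.5% with shuffled medians) had decided nothing. WT admixture had first been tested on genes also chosen for a low level in RPS26dC, which limited the share they could imply (a difference of 1.24 percentage points), and then by all 12 libraries, where 1 at 10.2% against a limit of 10% left it undecided. Fibroblast RNA had been left undecided by COL1A1, COL1A2 and COL3A1, which summed to 9.3% of CD44 and TNC, with 10.4% and 7.57% in the separate libraries on either side of the limit of 10%.

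RPS26dC libraries numbered 1 and 2 differed in the same direction in all 6 groups. Their deviations from the group means correlated with r of 0.16 to 0.33 in all 15 pairs of groups, against -0.017 to 0.087 in WT. WT material mixed into either number would bring all abundant WT transcripts. The 5 genes lowest against WT in the other number implied a WT share of 3.44% in the median group of number 1 and 3.07% in that of number 2, which argues against a share of 10% or more throughout either number. After thinning to equal totals 1915 genes were called, 1758 of the 1843 called before among them, which argues against depth. After removing the median of neighbouring genes 85.4% of calls stayed (87.5% with shuffled medians). That argues against copy number of segments of many genes, while smaller segments were not tested. The design gives no group that separates the numbers, so no biological explanation was tested, and the pattern stays open.

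The wide genotype difference in Input has more than a single possible source. Among 1295 called genes changed less than 4-fold in untreated cells, 30.3% stayed called after removing the median of neighbouring genes, against 81.4% with shuffled medians. The median size of the lost genes went from 0.96 to 0.51 with a median standard error of 0.25, and 34 of 256 windows of neighbouring genes lay beyond the shuffled limit, which is consistent with chromosome copy numbers that differ between the lines. For the 431 genes changed 4-fold or more, among them NEFM and IRS4, the local median made up 3.32% of the log2 change. The most extreme of the 256 windows had a median of 1.09, short of 4-fold. Both argue against copy number of segments holding most of the 50 genes of a window as the main source of these changes. A gain or loss of fewer genes would hardly move such medians, so smaller segments were not tested. IRS4 and TSC22D3, both lower, lie near each other on chromosome X. The abundant fibroblast transcripts COL1A2, DCN and LUM had 0 counts in both libraries of untreated RPS26dC Input, or 0% of CD44 and TNC. COL1A2 had been at 0 in the earlier test already. From the same list THY1, POSTN and PDGFRB also had 0 counts. Its members TAGLN (646 counts), COL1A1 (345), COL3A1 (105), COL5A1 (81), FBN1 (76) and ACTA2 (23) were counted there. The rewritten test therefore does not decide on fibroblast RNA. The labels name no independent clones, so whether the larger changes follow from the RPS26 edit or from differences between cell lines stays open.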

How the results depend on the processing

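The count of genotype differences in Input stayed within 1.5 times under every planned setting that kept all libraries, and Heavy against Light in untreated WT under all settings. Of the passing genes followed under each setting, 29 of 36 (untreated) and 31 of 36 (starved) genotype differences in Input, 22 of 22 in Heavy against Light, 10 of 18 in Heavy against Input, 13 of 24 in Heavy over Light on starvation in RPS26dC and 3 of 19 in WT also passed without each library, and none of those in the remaining comparisons. Where a group was left with 1 library it was assumed to vary like the others. The cause of the changes was not tested.

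Counts for starvation in Input (WT, RPS26dC) were 52 and 51 with DESeq2, 60 and 57 with no filter, 76 and 2 with only the compared groups, and for their difference 3 with no filter. Heavy over Input on starvation gave 56 and 95 with DESeq2, 16 and 63 with no filter, 92 and 0 with only the compared groups, 36 and 9 with Light in place of Heavy and 3 and 0 with the mean of Light and Heavy, and the untreated genotype comparison 1 with no filter. Heavy over Light on starvation gave 435 and 785 with DESeq2, 292 and 550 with no filter, 436 and 0 with only the compared groups, and in WT 171 with library totals and 53 with relative log expression. The genotype comparison of that ratio gave 20 (untreated) and 4 (starved) with DESeq2 and 25 and 4 with no filter. Heavy against Input gave 1408 with DESeq2 and 2200 with only the compared groups. Lists called fell from 93 to 21 with an estimated correlation.

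With a replicate block, starvation in Input gave 40 and 26, Heavy over Input in RPS26dC 43, Heavy over Light 259 and 577 and its untreated genotype comparison 2. With a culture replicate block, Heavy over Input gave 19 and 66, Heavy over Light 582 and 894, its untreated genotype comparison 25 and Heavy against Input 1758. With a genotype-specific replicate block, added after the data were seen, these were 30 and 64, 571 and 878, 19 and 1743, and starvation in Input 65 and 53. Also added after the data were seen, leaving out the numbered-1 RPS26dC libraries gave 52 for starvation in RPS26dC Input, 2 for the response difference, 49 for the untreated genotype comparison of Heavy over Light and 560 for its starvation in RPS26dC, and leaving out numbered-2 gave 5, 0, 3 and 63, and 15 for Heavy over Input in RPS26dC.

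Leaving out each library gave 761 to 934 and 941 to 1179 for the genotypes in Input, 0 to 8 and 0 to 17 for starvation in WT and RPS26dC, 0 to 0 for the response differences and both genotype comparisons of Heavy over Input, 0 to 1 and 0 to 28 for Heavy over Input on starvation, 0 to 2 and 0 to 1 for the genotypes in Heavy over Light, 6 to 31 and 41 to 607 for its starvation, 160 to 391 for Heavy against Input, 4693 to 4996 for Heavy against Light, 90 to 110 lists and 0.43 to 1.19 for the RPS26 difference.

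Most results whose sign turned lay near 0 and had not passed. Those that had passed were neuronal-lineage genes in untreated Input, G2 and mitosis genes in WT, and ATF4 (1.33), GAPDH (-1.20) and RACK1 (-1) in RPS26dC Heavy over Input on starvation. Ribosomal protein mRNAs in untreated Input (RPS26dC against WT) were 0.02 without numbered-2 libraries and -0.19 to 0.01 without a single library, and neuronal-lineage genes -0.07 to 0.30 without a single library. HSPA5 there was -0.18 without numbered-1 libraries and -0.20 to 0.22 without a single library. On starvation, G2 and mitosis genes in WT were -0.50 to 0.01 and MondoA and ChREBP targets -0.40 to 0.65 without a single library, and in RPS26dC the latter were -0.03 with library totals, -0.42 without numbered-1 libraries and -0.51 to 0.21 without a single library, and ER chaperones -0.03 without numbered-1 libraries and -0.02 to 0.12 without a single library. AMPK and mTOR genes in Heavy over Input were -0.03 and -0.04 without numbered-1 and numbered-2 libraries in untreated cells (-0.01 to 0.09 without a single library), and in starved cells -0.05 and -0.10, with -0.02 by library totals and by relative log expression, 0.00 with a replicate block and -0.13 to 0.06 without a single library. With Light in place of Heavy, ATF4 on starvation was -0.52 in WT (-0.09 with the mean) and -0.48 in RPS26dC, GAPDH 0.83 and RACK1 0.33. The ribosomal protein response difference was 0.01 without numbered-2 libraries, and these mRNAs in Heavy over Light on starvation in WT were 0.00 with the rotation test, -0.02 with library totals, 0.02 with relative log expression and -0.17 to 0.22 without a single library. DESeq2 gave no adjusted p for CAD (WT) and RRBP1 (RPS26dC) in Heavy over Input or SNRNP40 (WT) in Heavy over Light.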

Other observations

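Homeobox genes were looked at after their values were seen, with no enrichment test, and those that passed in Input were lower in RPS26dC. In untreated and starved cells, 3 and 7 of 11 HOXA genes, 5 and 6 of 9 HOXB genes, 4 and 4 of 8 HOXC genes and 3 and 3 of 8 HOXD genes were lower and 0 higher. Cluster medians were -1.13 and -1.32 for HOXA, -1.10 and -2.01 for HOXB, -0.85 and -1.19 for HOXC and -0.22 and -0.65 for HOXD. By chromosome, median genotype differences ran from -0.34 on chromosome 22 to 0.29 on chromosome 3 in untreated cells, and from -0.38 on chromosome 22 to 0.29 on chromosome 6 in starved cells.

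Long coding sequences gained in Heavy over Input on starvation, and ribosomal protein mRNAs lost. In untreated WT, genes of 6 kb or more lay -0.45 from those of 1.5 to 3 kb in Heavy over Input, and -0.30 in Heavy over Light, which is consistent with loss of the longest mRNAs from the Heavy fraction, as from polysomes that reach the bottom of the gradient. The partial correlation of the starvation change with 3' UTR length was 0.032 in WT and 0.12 in RPS26dC, against 0.29 and 0.31 for coding length, which argues against 3' UTR length rather than coding length as the source. Of 10000 random lists matched in coding length and level, the lower 2.5th percentile of medians was -0.27 in WT and -0.37 in RPS26dC, against -0.75 and -0.84 for ribosomal protein mRNAs, which argues against short coding sequences alone. A direct effect of starvation and loss of the longest mRNAs were not separated for the long messages, and that part stays open.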
